A study of Homo sapiens with 6 samples.

How the data were processed

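Gene expression was measured by RNA-seq in 6 libraries of cells labelled HepG2, 3 labelled as negative controls and 3 labelled as overexpressing APOA5 from a recombinant adenovirus. What the control cells received is not given in the sources used here. The labels call the libraries replicates by number but do not say whether they came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample labels.

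The deposited counts are whole-number read counts per gene, not normalised, 1 table per library, listed by NCBI gene identifier. The deposited FPKM values are fragments scaled for gene length and library total by the authors. Per the submitters' processing notes, TopHat2 2.1.0, Cufflinks 2.1.1 and HTSeq 0.6.1p2 were used, with the builds hg38 and GRCh38.p5, and the role of each tool and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and an overlapping antisense partner cannot be told apart. This bears on TONSL-AS1 and KCNQ1OT1, and on KRT8 and KRT18, which overlap on opposite strands of chromosome 12. Other genes may be affected too. Reads shared by near-identical copies could be split or dropped in counting, so values of HSPA1A (near-identical to HSPA1B), histone genes, FTL, FBXW10B, TUBB4B, CD24, MT2A and ribosomal protein genes are uncertain.

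The count data covered 34769 genes and the FPKM data covered 31101, of which 31100 were in both. Gene identifiers were matched to a RefSeq gene table (GRCh38.p14 assembly, used for names only), and 34389 matched. A set of 26 symbols turned into dates in the count table was read by identifier. Positions, transcript length and GC content came from GENCODE 29 on GRCh38, and 97.6% of the tested genes had a length and GC value. Some genes of the fixed lists have no row in the tables used, and these were not analysed here.

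Counts were tested with edgeR 4.0.16 under R 4.3.3, with TMM normalisation, the default filter on low counts by group, and the quasi-likelihood F-test with robust estimation, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Group levels are means of normalised CPM (counts scaled by the library total) with the SD over 3 libraries, and a log2 fold change is the libraries labelled APOA5 overexpression over control. For APOA5, the hepatocyte genes, the genes beside APOA5 and the abundant genes, CPM is the count over the total of the library. The standard error of a fold change was obtained from the fitted coefficient and its F statistic. For a count of 0, an upper limit of 3 counts over the library total was used, and intervals are exact binomial at 95%. These limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Total counts per library ranged from 7083843 to 8428431.

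A total of 35 gene lists was fixed before the data were examined, as was the test of each comparison. The 32 lists with at least 3 tested genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, two-sided, and Benjamini-Hochberg adjustment over the lists. Its p-values rest on that assumed correlation and on comparison with other genes, so they are not a measure of the spread between samples. A split of the libraries that mixed the labels called 0 genes and still passed 17 lists. Of the 10 lists past the threshold, 4 also passed with an estimated correlation. The second test, fry, passed 14 lists, which says only that their genes moved on balance one way, and its mixed form passed 28, which says only that genes in them changed in either direction. Several lists share genes, such as SESN2 and GDF15 in those of ATF4 and p53. The median, mean and test differed in sign for cholangiocyte and progenitor markers, immediate early genes, the list of genes around APOA5, glycolysis, nuclear oxidative phosphorylation, the HEK293 and neural list, and lipid droplets, none of which was past the threshold.

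The genes named in the text followed a rule fixed with the lists. It took APOA5 in every library, the 10 largest rises and 10 largest falls among genes past the threshold with at least 1 CPM in the higher group and non-overlapping groups, and the 5 highest-expressed genes in each direction with at least a 1.5-fold change. For each list it took up to 2 rising and 2 falling members with the smallest adjusted p, or, where no member passed, the 1 with the smallest p. The rule named 108 genes besides APOA5, of which the text gives those that it discusses, and some are not reported here. Names outside it (the liver and abundant genes, ZPR1, SIK3, GDF15, HSPA1B, INSR, IRS1, RMRP, CXXC1, ABLIM1 and LMNB2) were chosen after their values were seen.

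Alternatives were other normalisations, tests (DESeq2 1.42.0, limma-voom, edgeR without robust estimation) and filters, stricter thresholds, tests against a minimum fold, a replicate block, a gene-length correction, limma on the deposited FPKM, other set tests, and leaving out each library in turn. The FPKM test used log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, with a pseudocount of 0.1 and no filter as further alternatives, and its fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. FPKM results quoted in the text are from log2(FPKM + 1) with the filter. The edgeR test was tested on simulated data of the real 12695 genes, in which 200 genes were changed by known folds. It recovered 68.7% of the genes changed by 1.5-fold, 92.5% of those changed by 2-fold and all of those changed by 4-fold, with 184 calls of which 10 were false. The simulated counts were drawn independently for each gene, with no GC trend and no library apart from its group. In the real data 2970 genes were called, so these shares need not hold there. No sample was left out of the main comparison.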

Results

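The data were gene-level RNA-seq counts and FPKM values of 6 libraries from a human cell culture labelled HepG2, a line from a liver tumour that is widely used as a hepatocyte model. The labels describe insulin-resistant cells infected with a recombinant adenovirus for 48 h, and the title gives the purpose as the relation between overexpression of the apolipoprotein APOA5 and insulin resistance in hepatocytes. There were 3 libraries labelled control and 3 labelled APOA5 overexpression. Total counts were 7236994, 7454491 and 7083843 in the control libraries and 8428431, 8182577 and 8413184 in the libraries labelled APOA5 overexpression, so the ranges of the 2 groups did not overlap. Mitochondrially encoded genes took 26.4, 27.4 and 26.7% of the counts in the control libraries and 27.6, 23.1 and 22.2% in the others. Replicate 1 of the libraries labelled APOA5 overexpression stood apart within its group. Its chi-square per degree of freedom was 14 against replicate 3 and 8.25 against replicate 2, where the 3 control pairs gave 2.11 to 3.51. Replicates 2 and 3 of that group gave 4.10, above every control pair. Pairs across the 2 groups gave 14.7 to 19.8, so replicates 1 and 3 were nearly as far apart as libraries of different groups.

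The targeted gene was read first, because it checks the labels. APOA5 (gene 116519, chromosome 11, 116789367 to 116792420, minus strand, GENCODE 29 on GRCh38) had 0 counts in all 3 control libraries, and 0, 0 and 1 counts in replicates 1, 2 and 3 of the libraries labelled APOA5 overexpression. A count of 0 allows up to 0.402 to 0.423 CPM (the count scaled by the library total) in the control libraries and up to 0.356 and 0.367 CPM in replicates 1 and 2 of the other group. The single count is 0.119 CPM (exact 95% binomial interval 0.00301 to 0.662). The deposited FPKM of APOA5 was 0 in 5 libraries and 0.0324 in replicate 3 of the libraries labelled APOA5 overexpression. Overexpression of APOA5 was therefore not detectable at this depth in any of the 3 libraries that carry that label. Every direction given below is for the libraries as labelled. A total of 1 count is too few to show a difference between the groups for APOA5.

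Genes that mark hepatocytes were also near 0 in both groups. ALB, TTR and APOC3, which encode albumin, transthyretin and apolipoprotein C3, had 0 counts in all 6 libraries together, which allows up to 0.0641 CPM. APOA1 and transferrin (TF) had 2 counts each over the 6 libraries, and APOB and the liver transcription factor HNF4A had 1 count each. Of the 27 hepatocyte identity genes with a row, 1 reached a mean of 10 CPM, 7 reached 1 CPM, and 18 had under 10 counts in all. The protease inhibitor SERPINA1 was measured at 16.5 ± 2.66 CPM (SD, n = 6). The genes beside APOA5 on chromosome 11 were read in each library, ZPR1 at 40.6 ± 4.55, SIK3 at 22.9 ± 1.95 and BUD13 at 11.8 ± 4.24 CPM (SD, n = 6). Abundant transcripts included the scaffold protein gene AHNAK at 6368 ± 742 CPM, the keratin KRT8 at 1983 ± 319 CPM, CAV1 at 1174 ± 69.9 CPM, the receptor kinase AXL at 785 ± 68.1 CPM and the intermediate filament gene VIM at 511 ± 65.7 CPM (SD, n = 6). FPKM gave another order, with VIM at 2842 to 3296 and AHNAK at 148 to 186 over the 6 libraries. CPM is not scaled for gene length, but length was not shown to account for this order. In control replicate 1, KRT18 had 360 CPM and 1593 FPKM, where KRT8 had 1638 CPM and 1160 FPKM. The cause of this difference was not tested. The levels were those of cells with little or no transcript of many liver genes, in a culture labelled HepG2. The cell identity in the labels is therefore uncertain for everything that follows.

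**Figure D1:**
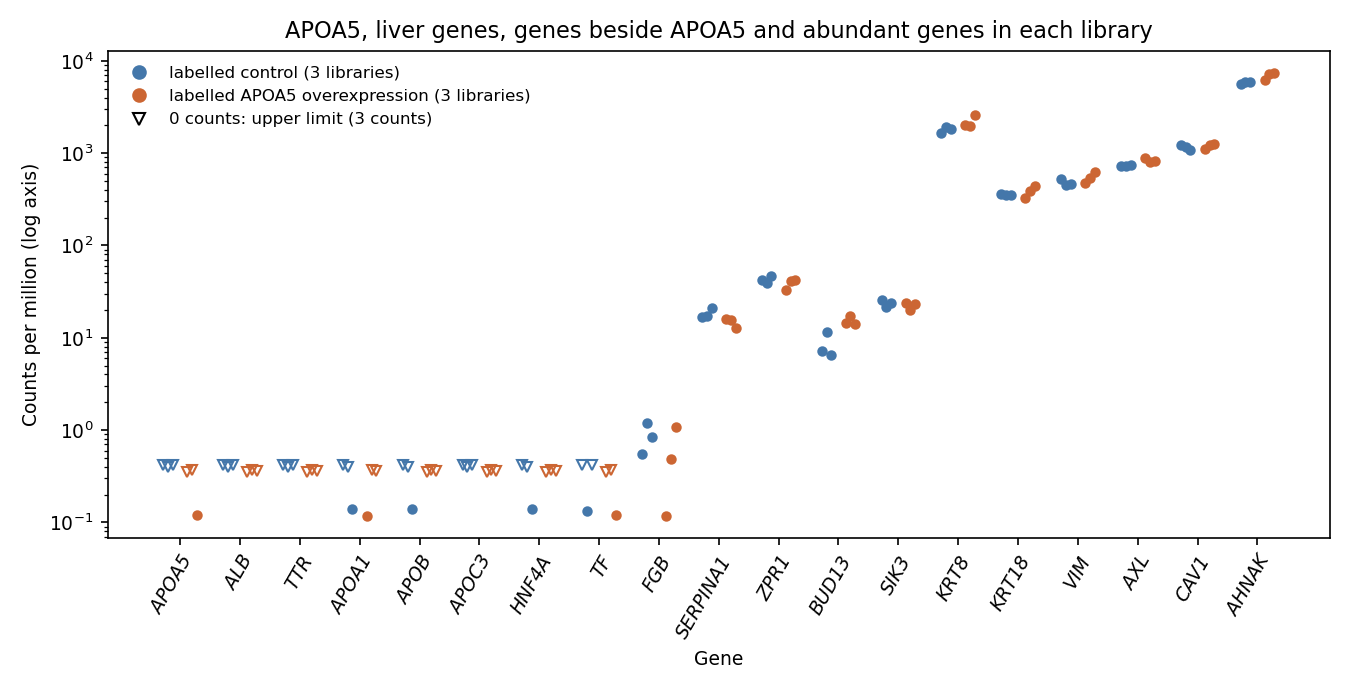
CPM of 19 genes (log axis) in the 6 libraries, blue for libraries labelled control and orange for those labelled APOA5 overexpression; filled circles are measured values and open triangles mark the upper limit that 0 counts allows. APOA5, ALB, TTR and APOC3 have triangles in nearly all libraries, while ZPR1, SIK3 and BUD13 lie between 6.49 and 46.6 CPM.

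The libraries labelled APOA5 overexpression differed from the control libraries in many genes. Of 12695 genes tested, 2970 changed, 1536 higher and 1434 lower (edgeR quasi-likelihood test, adjusted p under 0.05), which is 23.4%. Of these, 1242 changed by at least 1.5-fold (659 higher, 583 lower). The libraries of the 2 groups did not overlap for 38.8% of the tested genes, where chance gives 10% for 3 against 3. The proliferation marker MKI67 rose from 936 ± 50.5 to 2725 ± 237 CPM, a log2 fold change of 1.54 (SE 0.09, edgeR adjusted p = 4.86e-09), and the transglutaminase gene TGM2 rose from 852 ± 70.9 to 2249 ± 253 CPM (SD, n = 3). The DNA methyltransferase gene DNMT1 (chromosome 19, 10133345 to 10231286) rose from 45.5 ± 2.48 to 157 ± 3.85 CPM (log2 fold change 1.79, SE 0.09, edgeR adjusted p = 1.57e-09). The kinase gene MAPKAPK2 (chromosome 1, 206684944 to 206734283) rose from 13.9 ± 1.61 to 50.0 ± 4.36 CPM (log2 fold change 1.85, SE 0.12, edgeR adjusted p = 3.53e-08). In the other direction, the inducible chaperone gene HSPA6 (chromosome 1, 161524540 to 161526910) fell from 36.8 ± 13.6 to 2.54 ± 0.665 CPM, 14.5-fold lower (log2 fold change -3.86, SE 0.30, edgeR adjusted p = 2.38e-06).

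Most of the remaining genes with the largest changes were of low to moderate level. Rises were found for NIPAL4, CAMK2N2, the antisense RNA TONSL-AS1 (the strand setting is not given in the sources used here), RASSF3, SLC30A3, STIMATE, PAIP2B and the hemidesmosomal collagen gene COL17A1, with log2 fold changes from 1.74 to 2.06 and means of 1.42 to 6.78 CPM in the libraries labelled APOA5 overexpression. Falls were found for KITLG, which encodes the ligand of the receptor KIT, at -2.32 (SE 0.17), and for HSPA1A at -2.30 (SE 0.25). Reads of HSPA1A could be shared with the near-identical HSPA1B. Also lower were the angiopoietin gene ANGPT1 at -1.91 (SE 0.19), and FBXW10B, PLAC9, AATBC, SCG2, ABCA12 and LURAP1L, from -2.55 to -1.84. Among genes changed by at least 1.5-fold, the highest-expressed rising ones included MKI67, TGM2, the tubulin gene TUBB4B and the centromere gene CENPF at 0.77 (SE 0.08). The highest-expressed falling genes were the nuclear RNA MALAT1 (6888 ± 199 to 3835 ± 165 CPM, SD, n = 3), the ferritin light chain gene FTL, which has many pseudogenes, the binding protein gene IGFBP3 at -0.94 (SE 0.08), HMGA2 and ANKRD52. Calls for RASSF3, COL17A1, ABCA12 and MALAT1 were lost in the FPKM test (limma adjusted p = 0.16, 0.0645, 0.0985 and 0.209). NIPAL4, AATBC and PLAC9 were below the filter of that test. These genes lost their calls on FPKM without a filter (limma adjusted p = 0.0693, 0.0860 and 0.203). The fall of FTL was lost without replicate 1 of the libraries labelled APOA5 overexpression (log2 fold change -1.24, edgeR adjusted p = 0.0602, from 5.15e-07 to 0.0602 over the alternatives other than stricter thresholds). RASSF3 was at 0.698 ± 0.271 against 2.52 ± 0.129 CPM but at 15.7 ± 0.817 against 18.2 ± 0.976 FPKM (SD, n = 3). The number of lower genes was 947 without control replicate 2 and 915 without APOA5 overexpression replicate 2. In the FPKM test 69.6% of calls were higher (1234 higher, 539 lower) where 51.7% of the calls on counts were. That test used the deposited FPKM with no further scaling between libraries, unlike the test on counts. The median log2 fold change over the genes tested was 0.0478 on FPKM and -0.00288 on counts. Calls lost or gained on FPKM may reflect this shift, which was not tested.

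**Figure D2:**
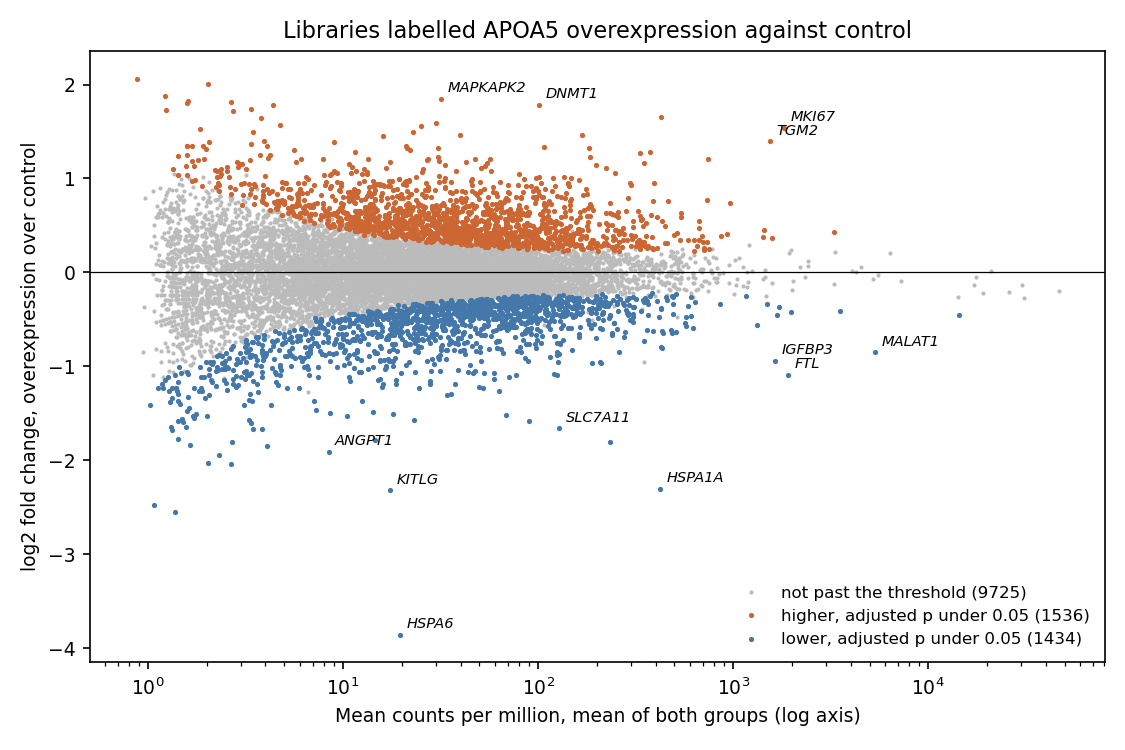
Each point is 1 of 12695 tested genes, with the mean of the 2 groups in CPM on the log horizontal axis and the log2 fold change of the libraries labelled APOA5 overexpression over control on the vertical axis. Orange marks 1536 higher and blue 1434 lower genes at an adjusted p under 0.05, and grey marks the others.

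**Figure D3:**
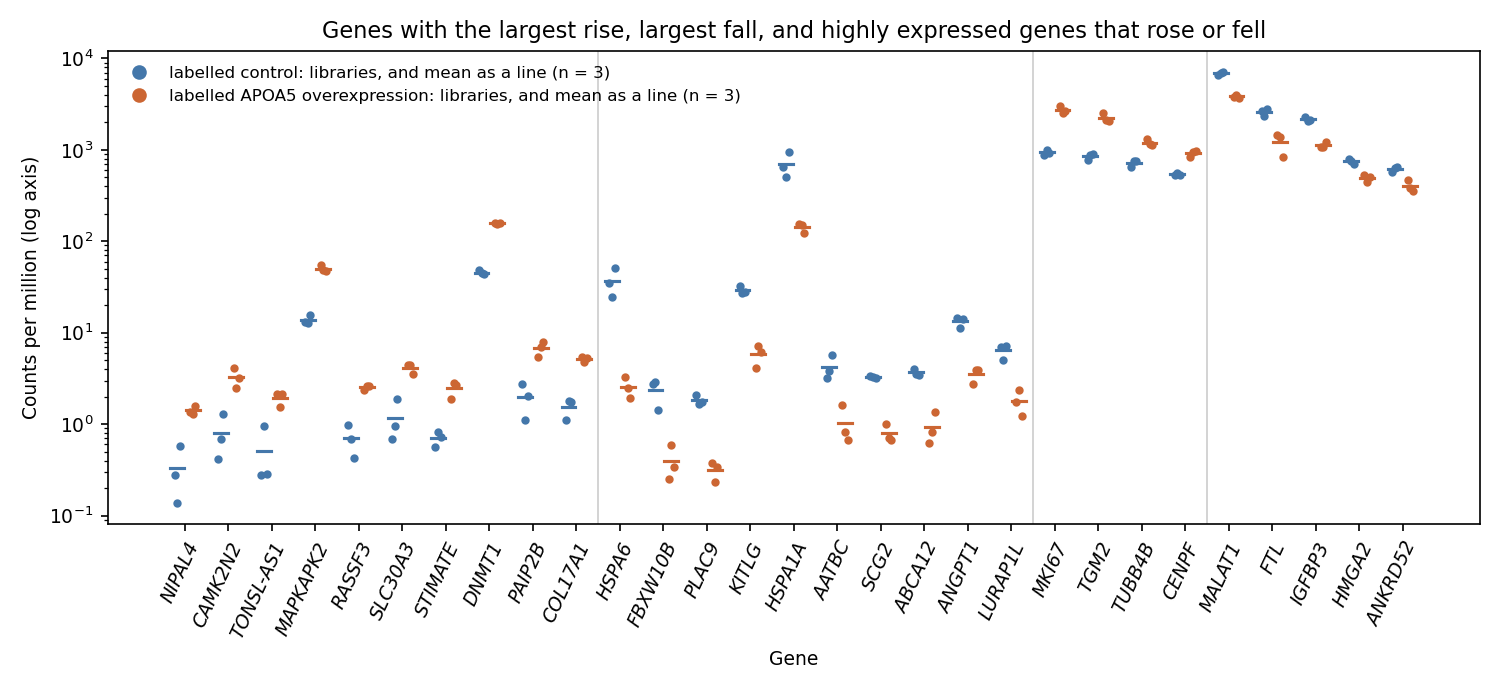
CPM (log axis) of 29 genes in each library, with the mean of each group as a line, for the 10 largest rises, the 10 largest falls, and genes among the highest-expressed that rose and that fell. MKI67 has means of 936 and 2725 CPM, and HSPA6 of 36.8 and 2.54.

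Genes of DNA replication and mitosis were higher. Among DNA replication and E2F targets, which drive entry into S phase, 27 of 29 tested members rose and 0 fell, with a median log2 fold change of 0.74 (camera adjusted p = 4.74e-29, and 27 rose when adjusted over the list alone). GINS1, a part of the replicative helicase, rose from 32.4 ± 2.90 to 70.04 ± 1.29 CPM, and its partner MCM7 from 36.6 ± 2.65 to 77.6 ± 4.95 CPM (SD, n = 3). Of the 26 mitotic genes, 24 rose and 0 fell, with a median of 0.67 (camera adjusted p = 5.74e-25, and 24 rose when adjusted over the list alone), including MKI67 and the survivin gene BIRC5 at 0.92 (SE 0.08, edgeR adjusted p = 7.62e-07). Both lists also passed with an estimated correlation (adjusted p = 0.0118 in each case).

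Targets of p53 were lower, and those of ATF4 were lower with the preset correlation only. Of 24 tested p53 targets, 17 fell and 0 rose, with a median log2 fold change of -0.44 (camera adjusted p = 1.55e-15, adjusted p = 0.0118 with an estimated correlation, and 20 fell when adjusted over the list alone). Among them were the antiproliferative gene BTG2, from 101 ± 2.80 to 35.4 ± 2.41 CPM, and the stress-response gene SESN2, from 134 ± 15.6 to 44.8 ± 5.37 CPM (SD, n = 3). Of 26 tested targets of ATF4, the transcription factor of the integrated stress response, 17 fell and 1 rose, the arginine transporter gene SLC7A1 at 0.50 (SE 0.08), with a median of -0.40 (camera adjusted p = 5.55e-11, but adjusted p = 0.0723 with an estimated correlation, and 18 fell and 3 rose when adjusted over the list alone). The cystine transporter gene SLC7A11 fell from 195 ± 12.4 to 61.6 ± 4.88 CPM (log2 fold change -1.66, SE 0.09, edgeR adjusted p = 3.32e-09). SESN2 and GDF15 stand in both lists. Without APOA5 overexpression replicate 3, 2 ATF4 targets rose.

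Replication-dependent histone genes and heat shock genes were lower in the set test with the preset correlation, but not with an estimated one. Of 12 tested histone genes, 8 fell and 0 rose, with a median log2 fold change of -0.98 (camera adjusted p = 5.35e-09, but adjusted p = 0.0739 with an estimated correlation, and 8 fell when adjusted over the list alone). The linker histone gene H1-2 fell from 34.4 ± 2.87 to 11.6 ± 1.53 CPM and H4C8 from 15.6 ± 1.65 to 5.39 ± 0.317 CPM (SD, n = 3), while H4C8 lost its call in the FPKM test (limma adjusted p = 0.276). The heat shock list had 10 members that fell and 2 that rose of 17 tested, with a median of -0.32 (camera adjusted p = 6.80e-05, but adjusted p = 0.368 with an estimated correlation, and the same 10 and 2 when adjusted over the list alone). HSPA6 and HSPA1A carried the largest falls of that list. The co-chaperone genes BAG3 and STIP1 rose by 0.31 and 0.36 on the log2 scale (edgeR adjusted p = 0.0142 and 0.0159). The rise of BAG3 lost its call without control replicate 1 and without control replicate 2 (edgeR adjusted p = 0.0727 and 0.0748, from 0.00353 to 0.0826 over the alternatives other than stricter thresholds). That of STIP1 was lost without control replicate 2 and without APOA5 overexpression replicate 3 (0.105 and 0.0624, from 0.000919 to 0.105 over the same alternatives). Of the heat shock list 6 fell without control replicate 3. The number that rose was 1 without control replicate 1 and without APOA5 overexpression replicate 3, and 0 without control replicate 2.

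Extracellular matrix genes shifted downward as a list. Of 28 tested matrix genes and targets of TGF-beta, 15 fell and 2 rose, with a median log2 fold change of -0.38 (camera adjusted p = 3.56e-07, adjusted p = 0.0295 with an estimated correlation, and the same 15 and 2 when adjusted over the list alone). The ligand gene TGFB2 fell from 166 ± 0.689 to 101 ± 0.652 CPM and the basement membrane collagen gene COL4A1 from 295 ± 20.8 to 186 ± 8.26 CPM, while ZEB1 rose by 0.39 on the log2 scale (SD, n = 3). The related ligand gene TGFB1 rose from 112 ± 15.9 to 153 ± 30.4 CPM (edgeR adjusted p = 0.0143). Its call was lost without control replicate 1 (0.0855, and from 1.66e-05 to 0.0884 over the alternatives other than stricter thresholds), and its log2 fold change went from 0.45 to 0.28 without APOA5 overexpression replicate 1. The call was also lost in the FPKM test (limma adjusted p = 0.0502) and with a replicate block and a gene-length trend removed (edgeR adjusted p = 0.0612). Without control replicate 1 the matrix list had 1 member that rose.

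NF-kB targets were lower with the preset correlation only. Of 24 tested, 9 fell and 3 rose, with a median of -0.31 (camera adjusted p = 0.000148, but adjusted p = 0.144 with an estimated correlation, and 14 fell and 3 rose when adjusted over the list alone). The adhesion receptor gene ICAM1 and the chemokine gene CCL5 fell by 0.95 and 0.83 on the log2 scale, and the inhibitor gene NFKBIE and the cytokine gene IL1B rose by 0.72 and 0.61. NRF2 targets had 6 that fell, HMOX1 among them at -1.09 (SE 0.10), and 1 that rose, TXNRD1, of 19 tested, with a median of -0.16 (camera adjusted p = 5.87e-05, but adjusted p = 0.332 with an estimated correlation, and 6 and 1 when adjusted over the list alone). The NRF2 median was -0.0321 without APOA5 overexpression replicate 1 and -0.37 without APOA5 overexpression replicate 3, where 11 of its members fell. The list of apolipoproteins and lipoprotein assembly had 31 genes with a row, of which 14 had under 10 counts in all. APOA1, APOB and APOC3 were among those 14, so the result does not cover them. Of the 12 tested genes of that list, 4 fell and 1 rose, with a median of -0.32. When adjusted over the list alone, 5 fell and 1 rose. The list had a camera adjusted p of 0.0275, but of 0.224 with an estimated correlation. This call was also lost without APOA5 overexpression replicate 2 (adjusted p = 0.0541), without a filter and in the FPKM test (from 0.00372 to 0.278 over the alternatives other than stricter thresholds). The receptor genes VLDLR and SCARB1 fell by 0.93 and 0.61 on the log2 scale, and SAR1B rose by 0.41 (edgeR adjusted p = 0.0139). The call of SAR1B was lost without control replicate 3 and without APOA5 overexpression replicate 2 (0.0824 and 0.0686) and in the FPKM test (limma adjusted p = 0.382).

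**Figure D4:**
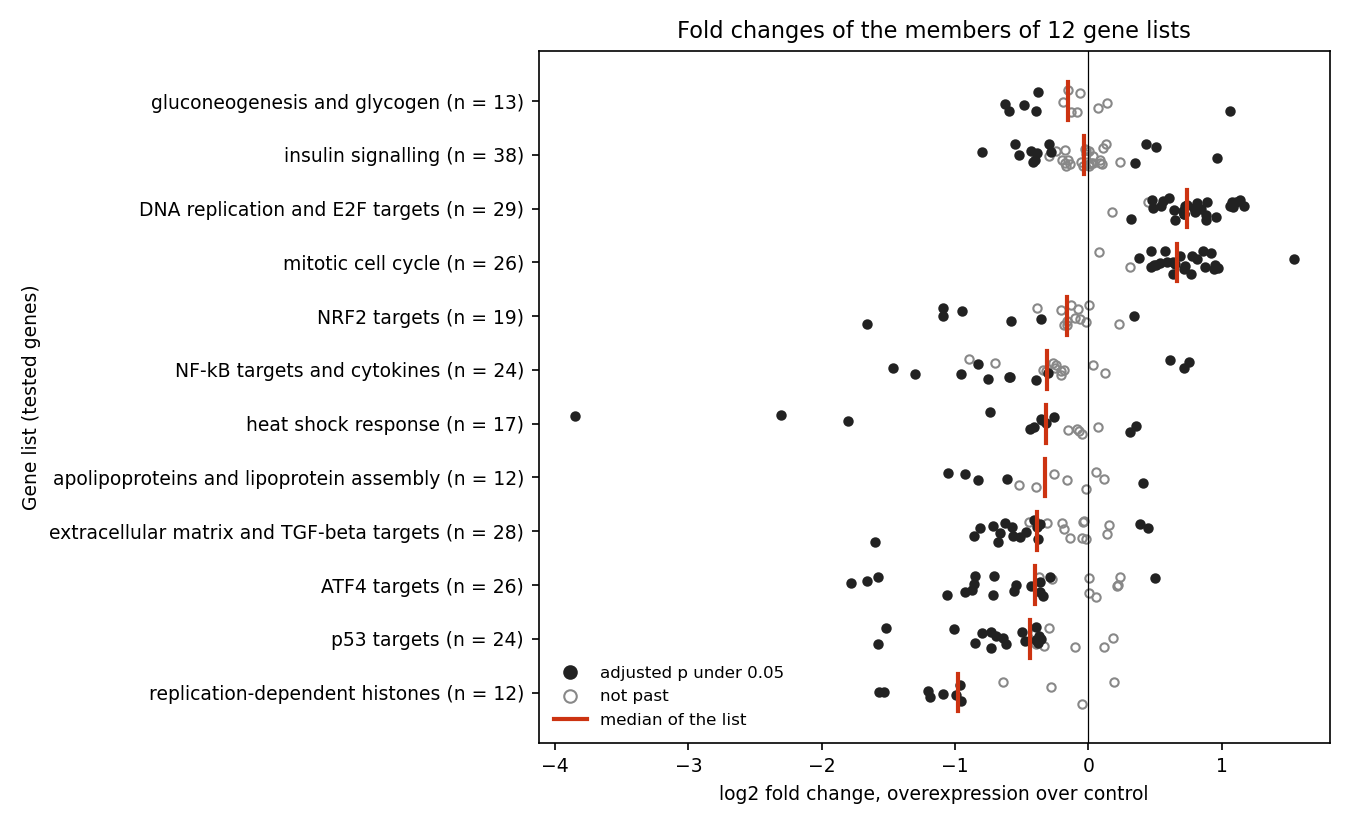
log2 fold change of each tested member of 12 gene lists (horizontal axis), the libraries labelled APOA5 overexpression over control; filled points passed an adjusted p of 0.05, open points did not, and the red bar is the median of the list. The replication list has its median at 0.74 and the histone list at -0.98.

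Insulin signalling, the subject of the title, was not past the threshold in the set test against other genes. Of 38 tested members, 4 rose and 9 fell, with a median log2 fold change of -0.03 (camera adjusted p = 0.269, adjusted p = 0.497 with an estimated correlation, and 4 rose and 9 fell when adjusted over the list alone). The cytokine signalling suppressor gene SOCS2 rose from 5.56 ± 1.02 to 10.9 ± 0.844 CPM, and the phosphatase gene PHLPP1 rose by 0.51 on the log2 scale. The kinase gene PRKCE fell from 102 ± 8.02 to 58.7 ± 3.71 CPM, and the lipid phosphatase gene INPPL1 from 124 ± 3.68 to 92.1 ± 9.81 CPM (SD, n = 3). INSR and IRS1, named after their values were seen because they encode the insulin receptor and its main substrate, fell by 0.42 (SE 0.12) and 0.38 (SE 0.09) on the log2 scale (edgeR adjusted p = 0.0152 and 0.00460), and the alternatives were not run for them. Among 13 genes of gluconeogenesis and glycogen, 1 rose, the glucose-6-phosphate transporter gene SLC37A4 at 1.06 (SE 0.15), and 5 fell, including the glycogen phosphorylase gene PYGL at -0.48 (SE 0.09) and the phosphatase subunit gene PPP1R3B at -0.40 (SE 0.09), with camera adjusted p = 0.215 and the same 1 and 5 when adjusted over the list alone. In fry, which asks only whether the genes of a list moved on balance one way, insulin signalling had an adjusted p of 0.0242 and gluconeogenesis one of 0.000534. The calls for PHLPP1, INPPL1 and PPP1R3B were lost in the FPKM test (limma adjusted p = 0.0534, 0.0502 and 0.0839). Without APOA5 overexpression replicate 2, 4 insulin signalling genes fell. Of the gluconeogenesis genes 3 fell without that library, without control replicate 2 and without control replicate 3.

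Lists of lipid metabolism did not pass the set test. In fatty acid and triglyceride synthesis 3 rose, AGPAT2 at 0.97 and ELOVL2 at 0.38 (a call lost in the FPKM test, limma adjusted p = 0.108) among them, and 1 fell of 27, with the same counts when adjusted over the list alone. The member that fell, the fatty acid synthase gene FASN, went from 54.3 ± 8.01 to 38.9 ± 1.05 CPM (edgeR adjusted p = 0.00482), but its FPKM went the other way, from 107 ± 19.0 to 186 ± 16.6 (SD, n = 3; limma adjusted p = 0.0132). Its direction depends on which of the deposited values is read. In cholesterol synthesis 3 rose, INSIG1 at 0.998 and FDFT1 at 0.38 (FPKM test, limma adjusted p = 0.0587) among them, and 1 fell of 21, STARD4 at -0.35 (edgeR adjusted p = 0.0457), whose FPKM did not fall (log2 difference 0.09). When adjusted over the list alone, 3 rose and 0 fell. The fall of STARD4 lost its call without control replicate 1, without control replicate 2 and without replicates 1 and 2 of the libraries labelled APOA5 overexpression (edgeR adjusted p = 0.16, 0.157, 0.129 and 0.0736). Over the alternatives other than stricter thresholds its adjusted p went from 0.0179 to 0.873. Its log2 fold change was -0.23 without APOA5 overexpression replicate 1. Fatty acid oxidation and PPARA targets had 3 that fell and 0 that rose of 25, ANGPTL4 at -0.74 among them. Of 14 genes of lipid droplets and lipolysis 1 fell, RAB18 at -0.52, and this and the oxidation list had the same counts when adjusted over the list alone. Of 8 tested bile acid and xenobiotic metabolism genes (28 with a row), 3 fell and 0 rose, with 3 when adjusted over the list alone. Among them the export pump gene ABCC2 fell from 166 ± 17.6 to 85.9 ± 5.40 CPM (SD, n = 3). The camera adjusted p of these lists were 0.302, 0.302, 0.499, 0.959 and 0.0840 in this order, and the bile acid list passed without control replicate 2 (adjusted p = 0.0246). Of the cholesterol genes 5 rose without APOA5 overexpression replicate 3 and 2 fell without control replicate 3. Of the oxidation genes 1 fell and 1 rose without control replicate 2, and 4 fell and 1 rose without APOA5 overexpression replicate 1. Of the lipid droplet genes 3 fell without APOA5 overexpression replicate 1, and 1 rose without control replicate 3 and without APOA5 overexpression replicate 3. Of the bile acid genes 2 fell when any library but APOA5 overexpression replicate 1 was left out.

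The other lists did not pass the set test. Of the hypoxia targets, 6 fell and 2 rose of 17, with VEGFA at -0.86 against BNIP3L at 1.01 and SLC2A1 at 0.75. SLC2A1 was also the only called member of 16 glycolysis genes, where 1 more fell without APOA5 overexpression replicate 3. Without control replicate 2 and without APOA5 overexpression replicate 2, 3 hypoxia targets fell. Among 29 interferon response genes, 4 fell and 2 rose, SAMD9L at -0.65 and OAS3 at 0.47 among them, both of which lost the call in the FPKM test (limma adjusted p = 0.0506 and 0.055). Of the interferon genes 1 rose without control replicate 2, control replicate 3, APOA5 overexpression replicate 2 or APOA5 overexpression replicate 3. Of 21 immediate early genes, 6 fell and 3 rose, with CCN2 at -0.81 and JUN at 0.55, and 6 and 4 when adjusted over the list alone. Endoplasmic reticulum chaperones had 4 that fell of 24, HERPUD1 at -0.50 (FPKM test, limma adjusted p = 0.138) among them, and 3 when adjusted over the list alone. Of these chaperones 2 fell without control replicate 1 or control replicate 2 and 1 without APOA5 overexpression replicate 2, and 2 rose without APOA5 overexpression replicate 1.

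The counts of called ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes depended on single libraries, though not every call in them did. They were 4 lower and 2 higher of 63 cytosolic ribosomal proteins, where 1 and 1 were past the threshold when adjusted over the list alone. The ribosomal counts were 4 higher without APOA5 overexpression replicate 1 and 1 higher when any other library was left out, and 1 lower without control replicate 1 and 2 lower without control replicate 3. RPL34 rose from 26.2 ± 2.54 to 59.0 ± 16.0 CPM (SD, n = 3; edgeR adjusted p = 4.01e-05) and kept its call in all 26 alternatives run for it. RPLP1, which rose, lost its call without control replicates 1, 2 and 3 and without replicates 2 and 3 of the libraries labelled APOA5 overexpression (edgeR adjusted p = 0.162, 0.146, 0.0521, 0.139 and 0.0662). RPL6, which fell, lost it without control replicates 1, 2 and 3 and without APOA5 overexpression replicate 3 (0.124, 0.0727, 0.0741 and 0.0985). RPLP1 lost it with DESeq2 too (adjusted p = 0.0601). RPLP1 and RPL6 lost it in the FPKM test (limma adjusted p = 0.763 and 0.526), where the ribosomal list passed the set test as lower (adjusted p = 0.000135). Counts were 2 lower and 1 higher of 44 nuclear oxidative phosphorylation genes, where 1 and 1 passed when adjusted over the list alone. The lower ones were 0 without control replicate 1, 1 without control replicate 2 or APOA5 overexpression replicate 2, and 4 without APOA5 overexpression replicate 3, and the higher ones 3 and 2 without replicates 1 and 2 of the libraries labelled APOA5 overexpression. Of 13 mitochondrially encoded genes, 2 were lower and 0 higher, ND3 and ND1. Without APOA5 overexpression replicate 1, 11 were lower and the list passed the set test (adjusted p = 1.08e-06). With all 6 libraries the list of mitochondrially encoded genes passed with limma-voom (adjusted p = 0.0251) and without a filter (adjusted p = 0.0379), and not in the main test (adjusted p = 0.0840). When any other library was left out 1 was lower, since ND1 lost its call (edgeR adjusted p = 0.0681, 0.0875 and 0.0658 without control replicates 1, 2 and 3, and 0.136 and 0.0937 without APOA5 overexpression replicates 2 and 3). The log2 fold change of ND1 was -0.45, and -0.69 without APOA5 overexpression replicate 1. ND1 also lost its call with DESeq2 (adjusted p = 0.139), and both ND3 and ND1 did in the FPKM test (limma adjusted p = 0.781 and 0.0841). Of the 8 nuclear RNAs and degradation signs, MALAT1 and KCNQ1OT1 fell and GAS5 rose, and of 3 metallothionein list genes MT2A rose and SLC30A1 fell. The call of GAS5 was lost when any library but APOA5 overexpression replicate 1 was left out (edgeR adjusted p = 0.0943, 0.125 and 0.0937 without control replicates 1, 2 and 3, and 0.123 and 0.127 without APOA5 overexpression replicates 2 and 3) and with DESeq2 (adjusted p = 0.0576). That of KCNQ1OT1 was lost when a gene-length trend was removed (0.492), and those of MALAT1 and MT2A in the FPKM test (limma adjusted p = 0.209 and 0.16).

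Of 6 tested genes beside or acting with APOA5, BUD13 rose from 8.56 ± 2.85 to 15.01 ± 1.59 CPM and SORT1 from 73.8 ± 3.40 to 98.6 ± 2.56 CPM (SD, n = 3). Counts adjusted over the list alone were the same as over all genes for the hypoxia, glycolysis, interferon, mitochondrially encoded, nuclear RNA, metallothionein and APOA5-related lists. The camera adjusted p of these lists, from hypoxia to the genes around APOA5, lay between 0.0840 and 0.959.

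Marker lists of cell types did not pass the set test. Of 6 tested hepatocyte identity genes, 0 changed, and the smallest p was that of FOXA2, at 1.78 ± 0.252 and 2.49 ± 0.412 CPM (SD, n = 3; edgeR adjusted p = 0.260). Of 7 fibroblast and stellate markers, PDGFRB and COL1A1 fell, at -1.22 and -0.74, and THY1 rose at 0.43 (edgeR adjusted p = 0.0147), a call lost without control replicate 1 and without control replicate 2 (0.0749 and 0.056) and in the FPKM test (limma adjusted p = 0.0942). Its log2 fold change was 0.24 without APOA5 overexpression replicate 1. Of 5 cholangiocyte and progenitor markers, CD24 fell from 121 ± 8.10 to 71.7 ± 2.29 CPM and KRT7 from 6.08 ± 0.618 to 3.60 ± 0.476 CPM (SD, n = 3). The fall of KRT7 lost its call without control replicate 1, without control replicate 3 and without APOA5 overexpression replicate 2 (edgeR adjusted p = 0.0531, 0.0583 and 0.0711) and with DESeq2 (adjusted p = 0.0506). Of 5 markers of HEK293 cells, a human embryonic kidney line in which the labels say the adenovirus was made, and of neural lineages, PAX2 rose from 16.7 ± 1.09 to 24.4 ± 2.64 CPM (SD, n = 3; call lost in the FPKM test, limma adjusted p = 0.115). All 4 lists had the same counts when adjusted over the list alone, and their camera adjusted p were 0.846, 0.209, 0.326 and 0.872 in this order. Without APOA5 overexpression replicate 1, 1 hepatocyte gene and 1 gene of the HEK293 list fell. The fibroblast list passed on FPKM (adjusted p = 0.0394). Acute phase proteins, endothelial markers and immune cell markers had 1, 2 and 1 genes with enough counts and were not tested as lists.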

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

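Settings chosen after seeing the data were leaving out mitochondrially encoded genes, thinning all libraries to the smallest total and removing a GC trend. The 2970 changed genes (1536 higher, 1434 lower) became 1638 (870 and 768) at an adjusted p under 0.01. They became 1221 (660 and 561) when tested against 1.2-fold and 176 (99 and 77) against 1.5-fold. These 3 settings ask for more by construction. With FPKM the numbers were 1773 (1234 and 539) with the filter, 1788 (1248 and 540) with a pseudocount of 0.1, and 1373 (950 and 423) without a filter, and the cause was not tested. The other settings that kept all libraries gave 2046 to 3858 genes, and DESeq2 gave 2378. Leaving out 1 library gave 2006 to 3187 genes, 1059 to 1629 higher and 915 to 1583 lower. The number of lower genes moved most without control replicate 2 (947) and without APOA5 overexpression replicate 2 (915), with fewer samples in the test. The 10 lists past the threshold became 4 with an estimated correlation, the cause of which was not tested, and 9 to 11 when 1 library was left out. No pairing of the samples by replicate number was seen, though the correlations that follow cannot exclude one. Deviations of samples with the same number correlated across genes at -0.18, 0.02 and -0.19, and with the number as a block 2145 genes were called, or 2046 with a gene-length trend also removed. APOA5 has too few counts for the filter, so it has a test value only where no filter was used, and lists were not tested against a minimum fold.

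Of the 108 genes named by rule, 31 kept their direction and side of the threshold under every alternative run for them, and 60 did so apart from the stricter thresholds. The other 48 lost a call elsewhere, 26 of them only on FPKM and 18 when 1 library was left out. The 9 lost only on FPKM without a filter were AATBC, ANGPTL4, INSIG1, NIPAL4, PLAC9, SCARB1, SLC2A1, SLC30A1 and VEGFA (limma adjusted p from 0.0507 to 0.203). Of these, AATBC, NIPAL4 and PLAC9 were below the FPKM filter, so no other FPKM test was run for them. With a replicate block and a gene-length trend removed, calls of GAS5, KCNQ1OT1, BAG3, STIP1, ND3, RPL6, RPLP1, STARD4, TGFB1, THY1 and TXNRD1 were among those lost, and without the GC trend those of ND1 and STIP1. Over genes and alternatives 2472 of 2788 values were the same, 310 lost the call and 6 reversed, all on FPKM. FASN was at 0.803, 0.809 and 0.803 and STARD4 at 0.0925, 0.095 and 0.0925 with the filter, the small pseudocount and no filter, and the cause was not tested. Of 831 list values, 780 were the same, 12 lost and 14 gained a call, and 25 turned the direction of the set test. The turned ones were all of lists not past the threshold, with adjusted p from 0.746 upward, and the cause was not tested. Their medians follow, in log2.

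Lipid droplets gave 0.0586 with limma-voom, 0.0524 and 0.0535 on filtered FPKM with the larger and smaller pseudocount, and -0.00748 to 0.0774 when 1 library was left out. Hepatocyte identity gave -0.165 without a filter, 0.283 with the filter at 1 CPM, -0.00558 on FPKM without a filter, and 0.106 to 0.382 when 1 library was left out. Metallothioneins gave -0.185 without a filter, 0.058 after thinning, 0.0584 without the GC trend, and -0.0735 to 0.209 when 1 library was left out. Nuclear oxidative phosphorylation gave 0.0603 without a filter and -0.0754 to 0.0727 when 1 library was left out. Glycolysis gave 0.0629 and 0.0643 on filtered FPKM, -0.0542 without the GC trend, and -0.0382 to 0.0284 when 1 library was left out. Endoplasmic reticulum chaperones gave 0.00803 on FPKM without a filter. The HEK293 and neural list gave -0.143 to 0.0705 when 1 library was left out. Depth limits what can be said of genes near 0, since 0 counts allow up to 0.423 CPM in the shallowest library.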

Other observations

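All tests below were chosen after the result was seen, except the thinning and GC tests of the replication, mitotic and p53 genes and the counts of other splits, which were set out before their values were known; the count with an estimated correlation was added after those with the preset one. Counts and FPKM gave log2 fold changes that correlated across 11837 shared genes at Pearson 0.78 and Spearman 0.80, and genes are not independent replicates. Of 2839 genes called on counts and present in both tests, 2755 had the same sign in FPKM and 84 the opposite, and 4 were called in opposite directions, FASN, CXXC1 (-1.48 on counts, 0.41 on FPKM), ABLIM1 (-0.65 and 0.53) and LMNB2 (0.60 and -0.41). Deviations from the gene means correlated with GC content across genes at -0.33 in control replicate 1 and 0.44 in APOA5 overexpression replicate 1.

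APOA5 and liver genes were near 0 in every library. The neighbours of APOA5, whose lowest value in any library was 6.49 CPM, argue against a loss of reads from the whole region. They cannot show whether reads of APOA5 itself were placed and counted. Lack of depth is argued against by the upper limits for APOA5, at most 0.423 CPM in the libraries with 0 counts and 0.662 CPM in the library with 1. A candidate explanation is that the libraries were made from cells other than the labelled HepG2. It stays open, since the count of hepatocyte identity genes at 10 CPM or more, which was 1, is part of the pattern itself, and so does a loss of liver transcripts in HepG2 cells, which was not tested. An APOA5 insert whose sequence the alignment could not place would also leave the count at 0, and was not tested.

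Replication and mitotic genes were higher and p53 targets lower, with 68 called members in that direction. After removal of the GC trend 68 of them were still past the threshold, which argues against that trend as the whole cause. After thinning to one depth 67 were. The members were chosen as called at full depth and the test already scales for depth. Thinning could therefore hardly come out otherwise, and it does not decide on depth. Groups made from different cell lines would differ by genes present in one group only, and 0 genes were at 10 CPM or more in one group and under 1 CPM in the other. A difference in growth state between the cultures was not tested, and neither was a difference in culture or library batch, since the labels give no batch. The labelled overexpression of APOA5 also stays open and untested, as APOA5 was not detected.

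Replication-dependent histone genes were lower while replication genes were higher. A lower share of cells in S phase would lead to lower replication and E2F targets, but 27 of 29 tested rose and 0 fell. That rise is part of the pattern itself, and the share of cells in S phase was not measured, so this explanation stays open. A lower capture of RNA without a poly(A) tail, which replication-dependent histone transcripts lack, could account for the pattern and cannot be told apart from other causes, because only 1 of the 14 such RNAs listed had enough counts to test. That RNA, RMRP, was at 60.8 ± 11.4 CPM in control and 44.5 ± 7.65 CPM in the other libraries (SD, n = 3; log2 fold change -0.45, edgeR adjusted p = 0.0241), but at 356 ± 12.4 and 335 ± 26.0 FPKM (log2 difference -0.09, limma adjusted p = 0.488). Reads shared between histone copies were not tested.

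There are 10 ways to split the 6 libraries into groups of 3, too few for a share under 0.05. For genes, 1 of the 10 splits gave as many as the real value of 2970, and the highest other split gave 0. For lists, 4 of the 10 splits gave as many as the real 10, and the highest other split gave 17. With an estimated correlation the real split gave 4 lists and the highest other split 0, and 1 of the 10 splits gave as many. Each group of every other split holds a majority of one label, and the replication list passed in 9 and the p53 list in 9 of the 9 other splits. Mitotic genes passed in 8, ATF4 targets and histones in 6 each, and NF-kB targets in 5. Matrix and heat shock genes passed in 4 each, NRF2 targets in 3 and apolipoprotein genes in 1. The smallest camera adjusted p in another split was 0.000115 for heat shock genes (real 6.80e-05) and 0.0274 for apolipoprotein genes (real 0.0275). Retained labels do not account for all of these calls. Cytosolic ribosomal proteins passed in 5 other splits (smallest adjusted p = 2.65e-06, real 0.269), mitochondrially encoded genes in 3 (2.05e-09, real 0.0840) and nuclear oxidative phosphorylation in 3 (0.00135, real 0.872).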
